A study of Mus musculus with 8 samples.

How the data were processed

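Poly(A) RNA of ventricular heart tissue from 8 mouse samples was sequenced on an Illumina NovaSeq after fragmentation and random-hexamer priming, per the labels' protocols. The submitters' processing notes name cutadapt, RSEM 1.3.1, limma and the genome build GRCm38, without saying which step used which; the annotation and the strand setting are not given in the sources used here. The labels put 3 samples in C, 3 in DKO and 2 in KO, the latter numbered 1 and 3; a KO sample number 2 was not analysed here. Nothing in the labels says that the samples come from separate animals, so p-values measure only the spread between these samples, which may be technical. Replicates of a group differed by more than read-counting noise (chi-square per gene 13.7 to 256.1), so none is a copy of another column or a second read-out of the same library; this covers counting error only and does not tell whether libraries share an animal.

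The deposited table gives a normalised signal for 13677 genes in 8 columns. Each deposited signal value is a number of reads plus 0.5, in proportion to an effective library size (the scale of CPM), as read from the values: every value was an odd multiple of its column's smallest value, so whole reads were recovered for 100% of values within a tolerance of 0.001 reads. The effective size is the total times a scaling factor, and factors computed again from the recovered reads with edgeR's TMM method differed from the deposited ones by 0%. Factors were 0.925 to 0.964 in C, 0.705 to 1.06 in DKO and 1.36 to 1.37 in KO. Totals over the table were 17212475 to 17648456 reads in C, 15028176 to 20561196 in DKO and 18506002 and 21202385 in KO. At these depths 3 reads, the limit that a count of 0 allows, correspond to a signal of 0.104 to 0.283 in a library; this covers counting error only. Genes with low values appear to be absent from the table, which was not stated. RSEM estimates can split reads between near-identical copies, so values of pseudogenes and close paralogs are uncertain.

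Gene names are those of the table, and 11 rows without a name keep their identifier. Coordinates and transcript lengths come from GENCODE M21, which is on GRCm38, the build in the processing notes; 13671 of 13677 identifiers matched. Lengths and GC content are those of the longest annotated transcript.

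The tests, the gene lists and the rule for named genes were fixed before the data were examined. They allowed for normalised counts or CPM, and since the values are on the scale of CPM the minimum of 1 applied. The 13544 genes with a value of at least 1 in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), in a model of 3 group means over all 8 libraries with 5 residual degrees of freedom and an intensity trend in the variance. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. In text, a fold is 2 to the power of the log2 fold change.

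Of 31 gene lists, 30 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over 90 tests (30 lists in 3 comparisons); sex-linked genes were read as values only. The lists covered the VHL and HIF pathway, hypoxia response, glycolysis, fatty acid oxidation, oxidative phosphorylation, mitochondrial transcripts, contractile genes, cardiac stress genes, ion channels and conduction, calcium handling, extracellular matrix, angiogenic signalling, integrated stress response, proliferation, interferon response, antioxidant response, and markers of epicardium, fibroblast, endothelium, mural cells, macrophage, lymphocyte, neutrophil, erythroid cells, atrium, adipocyte, skeletal muscle, neurons and glia, immediate early genes and the circadian clock. The lists from epicardium to the circadian clock were planned as markers of other cell types or of handling. Some genes, such as Postn, Loxl2, Slc2a1 and Col1a1, are in several lists, so the lists are not independent. Camera with an estimated correlation and fry were alternatives. The named genes are Vhl, Hif1a, Epas1 and Wt1; in each comparison the 8 genes per direction with the largest fold change among those past the threshold, with a mean level at or above the median of tested genes (13.1) and no overlap between the groups' libraries, passing over unnamed and predicted genes; and up to 3 members of each list past the threshold with the largest change, or the member with the smallest p where none passed. The text gives a part of these, mainly of lists that passed, and some are not reported here. All 21 genes of DKO versus C, Gm8730, Gm9625, Rplp0, Mt2 and Rad9b were named as well, some outside the rule and after their values were seen.

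The scripts were tested on simulated reads for 13276 genes, with 100 genes changed at each size in KO and another 100 in DKO. In KO versus C 59% of changes of 1 on the log2 scale and 99% of changes of 2 were recovered, and 3.66% of calls were false. In DKO versus C the shares were 67% and 99%, with 6.21% false, and in DKO versus KO 62% and 99%, with 4.97% false. A list shifted in KO was called in both comparisons with KO, with no other list. Genes were simulated independently, so this does not show how often camera calls lists whose genes vary together. Each gene was also given the same spread in all groups. In the data, replicates differed more in DKO (chi-square per gene 55.5 to 256.1) than in C (13.7 to 29.4). The recovered shares may therefore be too high for DKO versus C.

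Overlaps between comparisons that share controls were set beside 100 simulated draws without change. Alternatives were other pseudocounts (0.25 and 5), no filter or a minimum of 5, quantile normalisation, median centring, no variance trend, a robust fit, library weights, the 2 groups alone, the replicate number as a block, each library left out, other thresholds, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads and, chosen after seeing the data, limma's voom on the recovered reads, the mitochondrial transcripts left out with the scaling computed again, and the trend of transcript length and GC content removed per library.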

Results

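RNA sequencing of mouse ventricular heart tissue gave 8 libraries in 3 groups, named here as in the labels: C (n = 3), KO (n = 2) and DKO (n = 3). The series compares ventricles deficient in Vhl with wild-type ventricles in mice that express Cre recombinase under Wt1, a gene of the epicardium. Vhl encodes the von Hippel-Lindau protein, the subunit of a ubiquitin ligase that marks the alpha subunits of hypoxia-inducible factors for degradation when oxygen is present. The labels do not spell out the 3 abbreviations or say which second change the DKO samples carry, so every direction is one between libraries labelled C, KO and DKO. The table held 15028176 to 21202385 reads per library, and levels are given in units of the deposited signal as mean ± SD, with n = 3 for C, n = 2 for KO and n = 3 for DKO. Transcripts of the mitochondrial genome took 25.5% ± 3.07 of the reads in C, 16.8% ± 0.811 in KO and 31.5% ± 9.46 in DKO. The library DKO 2 stood apart, with 41.6% mitochondrial reads and 51.5% of its reads in its 10 most abundant genes, against 22.0% to 38.1% in the other 7 libraries.

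The level of Vhl mRNA (ENSMUSG00000033933, chromosome 6, 113623959 to 113631633, GRCm38) was not lower in the libraries labelled KO or DKO. It was 7.91 ± 0.925 in C, 8.64 ± 0.450 in KO and 10.3 ± 1.43 in DKO. The difference between KO and C was 0.12 ± 0.18 (SE) on the log2 scale (limma, adjusted p = 0.71), and that between DKO and C was 0.33 ± 0.16 (SE) (limma, adjusted p = 0.59). The whole-gene level therefore did not check the labels in this tissue. The labels give neither the exons removed nor the share of ventricular cells in which Cre acted.

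In the libraries labelled KO, set against those labelled C, 16 of 22 cardiac stress genes and 32 of 36 extracellular matrix genes rose, and 27 of 42 oxidative phosphorylation genes fell. These list calls had adjusted p = 0.19, adjusted p = 0.47 and adjusted p = 0.56 with an estimated correlation. Myh7, which encodes the beta myosin heavy chain of fetal and stressed ventricles, was 1213 ± 8.99 in KO against 98.7 ± 23.4 in C, a 12.4-fold rise (limma, adjusted p = 2.81e-05). Postn, encoding the matrix protein periostin, rose 8.004-fold from 22.5 ± 7.29 to 182.7 ± 38.5 (limma, adjusted p = 0.000203). Nppa, the gene of atrial natriuretic peptide, rose 6.92-fold from 298.7 ± 114.3 to 2023 ± 565 (limma, adjusted p = 0.000895). Tesc, encoding the calcium-binding protein tescalcin, fell by 2.42 on the log2 scale, from 385.4 ± 15.3 to 71.2 ± 6.59 (limma, adjusted p = 0.000122).

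**Figure D1:**
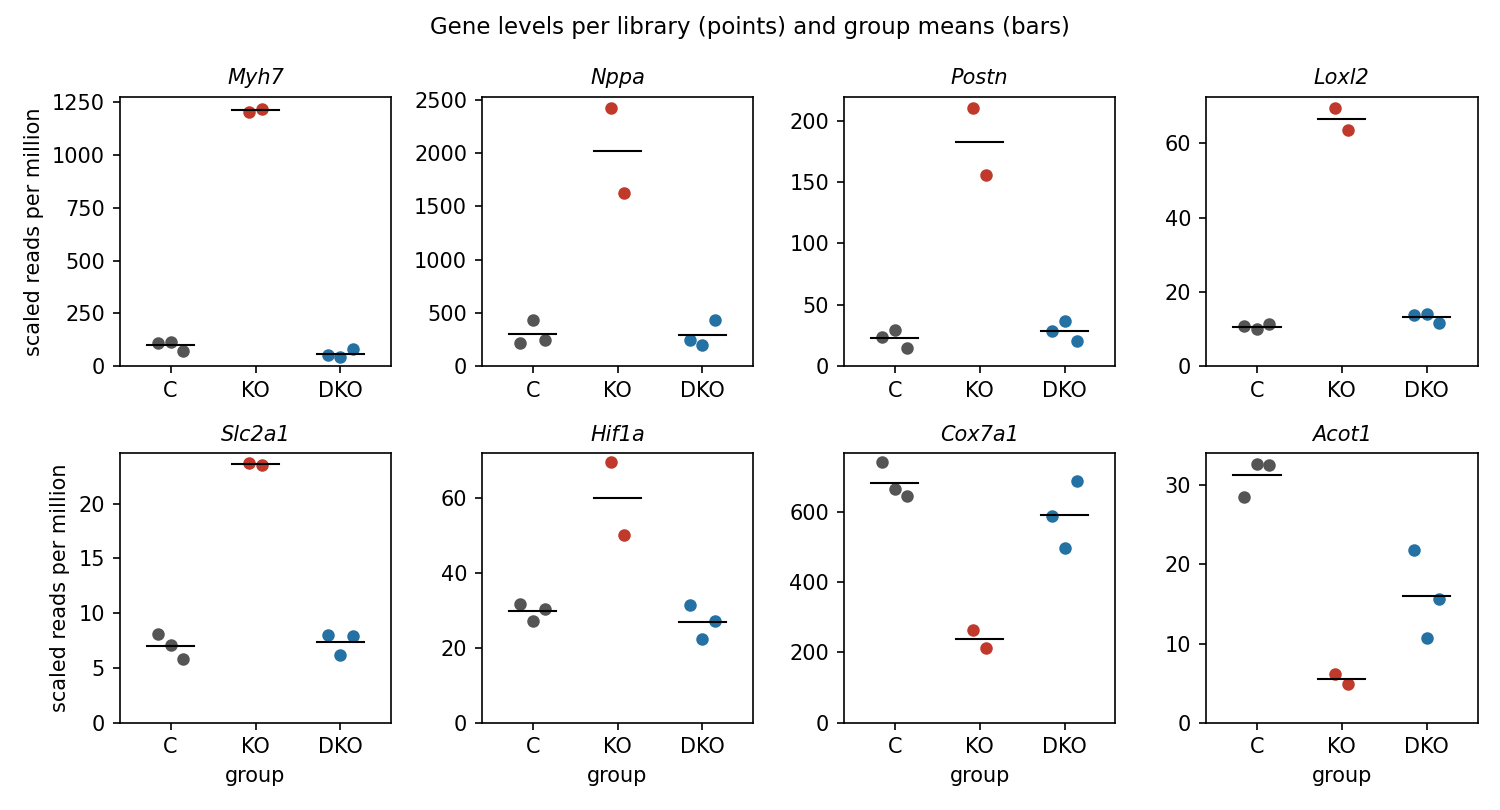
Levels of 8 named genes in units of the deposited signal (vertical axis, linear, from 0) in the groups C, KO and DKO. Points are libraries and bars are group means, and both KO points of Myh7, Nppa, Postn, Loxl2, Slc2a1 and Hif1a lie above those of the other libraries, while both KO points of Cox7a1 and Acot1 lie below them.

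Among 36 extracellular matrix genes 32 rose in KO and 0 fell (33 rose when adjusted over the list alone), with a median log2 fold change of 1.31. The list passed camera with adjusted p = 7.05e-24, and had adjusted p = 0.47 with an estimated correlation. Ltbp2, which encodes a latent TGF-beta binding protein, rose from 3.04 ± 0.832 to 33.2 ± 10.8, and the collagen gene Col12a1 rose from 0.703 ± 0.127 to 9.96 ± 1.36. Col14a1 (7.35 ± 1.64 in C, 45.4 ± 4.41 in KO) and Col18a1 (15.2 ± 3.19 in C, 71.1 ± 12.9 in KO) were among the 8 largest rises of well-expressed genes. In the fibroblast list 8 of 19 genes rose and 0 fell (8 rose and 1 fell when adjusted over the list alone). Col1a1 went from 63.5 ± 7.53 to 243.7 ± 20.3 and Mfap5 from 19.1 ± 3.28 to 61.2 ± 10.002. The fibroblast list had camera adjusted p = 0.000573 and adjusted p = 0.69 with an estimated correlation. In the epicardium list 5 of 11 tested genes rose and 0 fell (5 rose when adjusted over the list alone). They were led by the keratin gene Krt19 (0.192 ± 0.184 in C, 7.47 ± 2.74 in KO) and the sulfatase gene Sulf1 (11.1 ± 1.96 in C, 30.0 ± 3.39 in KO). This list had camera adjusted p = 0.0283 and adjusted p = 0.61 with an estimated correlation. The epicardium call ended without C replicate 3 (adjusted p = 0.0819) or KO replicate 3 (adjusted p = 0.0713). Wt1 itself was 3.42 ± 1.19 in C and 7.32 ± 0.422 in KO (limma, adjusted p = 0.0302). Its call ended without C replicate 1 (adjusted p = 0.109), C replicate 3 (adjusted p = 0.0883), KO replicate 1 (adjusted p = 0.163) or KO replicate 3 (adjusted p = 0.146).

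Of 22 cardiac stress genes 16 rose in KO and 0 fell (19 rose when adjusted over the list alone), with a median log2 fold change of 1.62. The list passed camera with adjusted p = 5.59e-14 and had adjusted p = 0.19 with an estimated correlation. Besides Myh7, Nppa and Postn, Ankrd1, encoding a stretch-responsive ankyrin repeat protein of muscle, rose 6.82-fold from 388.3 ± 136.5 to 2612 ± 769.8 (limma, adjusted p = 0.00318).

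In the hypoxia response list 16 of 44 genes rose in KO and 2 fell (22 rose and 3 fell when adjusted over the list alone). The list had camera adjusted p = 1.79e-06 and adjusted p = 0.065 with an estimated correlation. Loxl2, a lysyl oxidase of the matrix, rose 5.82-fold from 10.6 ± 0.698 to 66.6 ± 4.26 (limma, adjusted p = 6.84e-06). The lactate transporter gene Slc16a3 rose from 3.34 ± 1.05 to 17.97 ± 1.78, and the glucose transporter gene Slc2a1 from 7.01 ± 1.14 to 23.6 ± 0.114. The glycolysis list did not pass as a list: 6 of 26 genes rose and 3 fell (8 rose and 4 fell when adjusted over the list alone; camera, adjusted p = 0.37). In the VHL and HIF pathway list 2 of 13 genes rose and 3 fell (the same numbers when adjusted over the list alone; camera, adjusted p = 0.99). Hif1a rose from 29.8 ± 2.32 to 60.0 ± 13.8 (limma, adjusted p = 0.00695; adjusted p = 0.0856 without KO replicate 1). Egln3, a HIF prolyl hydroxylase gene, rose from 40.3 ± 4.52 to 81.8 ± 10.6 (limma, adjusted p = 0.00571; adjusted p = 0.0822 without KO replicate 3). Epas1, encoding HIF-2 alpha, was 318.3 ± 25.01 in C and 283.2 ± 30.4 in KO (limma, adjusted p = 0.61).

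Among 42 nuclear genes of oxidative phosphorylation 27 fell in KO and 0 rose (35 fell when adjusted over the list alone), with a median log2 fold change of -0.96. The list had camera adjusted p = 2.84e-16 and adjusted p = 0.56 with an estimated correlation. Ndufa1, a complex I subunit gene, went from 311.8 ± 39.1 to 105.6 ± 35.0, and Cox7a1, a cytochrome c oxidase subunit gene of heart and muscle, from 684.2 ± 50.9 to 237.7 ± 37.4. Across genes, which are not independent, the change in KO also went with transcript length (rank correlation 0.25). A group of 80 cytosolic ribosomal protein genes, short transcripts looked at after the values were seen, had a median of -0.75 with 53 lower and 0 higher. That median was negative under each scaling tried, from -0.80 with median centring to -0.41 with the trend of length and GC content removed. In the fatty acid oxidation list 12 of 31 genes fell and 1 rose (15 fell and 1 rose when adjusted over the list alone). It had camera adjusted p = 6.17e-09 (adjusted p = 0.59 with an estimated correlation). The thioesterase gene Acot1 went from 31.3 ± 2.34 to 5.48 ± 0.909, the uncoupling protein gene Ucp3 from 81.1 ± 16.2 to 18.3 ± 2.92, and Pdk4, encoding a kinase that restrains pyruvate dehydrogenase, from 547.9 ± 54.5 to 171.4 ± 59.6. Of 13 transcripts of the mitochondrial genome 5 fell and 0 rose (6 fell when adjusted over the list alone). That list had camera adjusted p = 9.29e-05 and adjusted p = 0.60 with an estimated correlation. Its call ended once the length and GC trend was removed (adjusted p = 0.0525). Of 24 contractile genes 3 fell and 1, Myh7, rose (the same numbers when adjusted over the list alone). Tnnt1 went from 21.4 ± 1.75 to 9.70 ± 0.434. The contractile list had camera adjusted p = 0.0283 and adjusted p = 0.78 with an estimated correlation. Its direction turned under quantile normalisation (adjusted p = 0.0804). The contractile call ended without C replicate 2 (adjusted p = 0.0754), without KO replicate 1 (adjusted p = 0.0930) or with the length and GC trend removed (adjusted p = 0.0570).

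Of 15 skeletal muscle genes 12 fell in KO and 1 rose (12 fell and 2 rose when adjusted over the list alone), with a median log2 fold change of -3.84, or -3.92 with genes without reads in KO set at their bound. The skeletal muscle list had camera adjusted p = 1.33e-09 and adjusted p = 0.47 with an estimated correlation. Myh4, a myosin heavy chain of fast skeletal fibres, was 70.5 ± 55.2 in C and had 0 reads in both KO libraries. It was thus at least 1275-fold lower than in C against a floor of 3 reads over the group. Atp2a1, encoding the calcium pump of fast fibres, went from 44.8 ± 35.0 to 0.164 ± 0.0374. The 3 C libraries differed widely in these genes, with Myh4 at 66.5, 17.4 and 127.6. Of 28 proliferation genes 8 rose (11 rose and 1 fell when adjusted over the list alone). That list had camera adjusted p = 1.83e-06 and adjusted p = 0.065 with an estimated correlation. Of 25 immediate early genes 10 rose (12 when adjusted over the list alone), with Ier3 going from 15.4 ± 1.03 to 54.3 ± 9.90. That list had camera adjusted p = 2.89e-07 and adjusted p = 0.47 with an estimated correlation. Of 23 macrophage genes 4 rose (10 when adjusted over the list alone; camera, adjusted p = 0.00536; adjusted p = 0.61 with an estimated correlation). Of 13 adipocyte genes 5 fell (6 when adjusted over the list alone; camera, adjusted p = 0.000686; adjusted p = 0.47 with an estimated correlation).

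**Figure D2:**
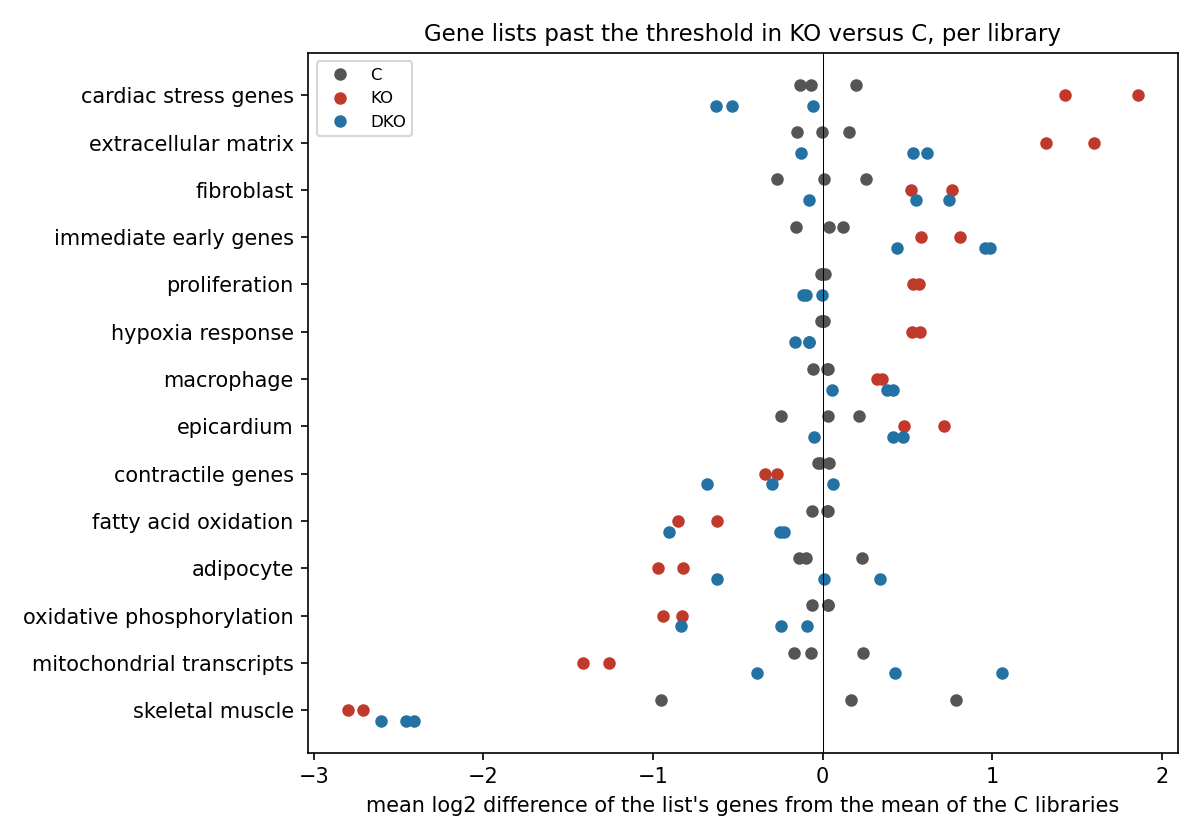
Mean log2 difference of each list's genes from the mean of the C libraries (horizontal axis) for the 14 lists past the threshold in KO versus C (vertical axis), with a point for each library of C, KO and DKO. Both KO libraries lie at or above 1.32 for the extracellular matrix, and DKO 2 lies at -0.84 for oxidative phosphorylation, beside -0.24 and -0.09 in DKO 1 and DKO 3.

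In all, 1883 of 13544 tested genes changed between KO and C in limma at an adjusted p of 0.05, 934 higher and 949 lower in KO, and 713 of them by at least 2-fold. No list call held with an estimated correlation, and the remaining 16 lists did not pass, with camera adjusted p from 0.0683 to 0.99. The count was 783 without KO replicate 1, 449 without KO replicate 3, 899, 1048 and 985 without C replicate 1, 2 and 3, and 2966 without DKO replicate 2.

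The comparison of DKO with C gave few changed genes, but the DKO libraries varied widely. Their log2 values correlated with each other at 0.966 to 0.977 (Pearson), while DKO 3 correlated with the C libraries at 0.980 to 0.985. Few calls therefore do not show that DKO was like C. Among 25 immediate early genes 5 rose in DKO, and among 15 skeletal muscle genes 8 fell. These list calls had adjusted p = 0.47 and adjusted p = 0.10 with an estimated correlation. Both lists were among those planned as markers of other cell types or of handling. Whether handling differed between the groups was not tested. Fos, a transcription factor gene of the immediate early response, rose 9.48-fold from 3.54 ± 1.98 in C to 40.9 ± 16.3 in DKO (limma, adjusted p = 0.00213). Fosb rose 15.1-fold from 0.741 ± 0.279 to 27.8 ± 13.7 (limma, adjusted p = 0.000504; adjusted p = 0.0813 with voom, chosen after seeing the data). The heat shock gene Hspa1b rose 4.55-fold from 2.47 ± 0.575 to 14.8 ± 2.84 (limma, adjusted p = 0.000504), and Arc rose from 1.60 ± 0.208 to 11.003 ± 1.72 (limma, adjusted p = 0.000504). Pdk4 fell by 1.85 on the log2 scale, from 547.9 ± 54.5 to 156.6 ± 55.3 (limma, adjusted p = 0.0126; adjusted p = 0.0659 without C replicate 1 and 0.0661 without C replicate 3).

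Of the 21 genes that changed between DKO and C in limma, 10 were higher and 11 lower, against 1151 genes at an unadjusted p under 0.05. The other 6 higher genes were Hspa1a, Nr4a1, Pm20d1, Pla2g4e, Foxo6 and the long noncoding RNA gene Gm26917. Hspa1a and Hspa1b are near-identical copies, so their reads can be split uncertainly between them. The lower genes were Pdk4, Mt2, Shld1 and 8 of the 15 skeletal muscle genes (Pvalb, Actn3, Tnnc2, Ryr1, Atp2a1, Myh1, Myh4 and Tnnt3; 14 fell when adjusted over the list alone). The skeletal muscle list passed camera with adjusted p = 2.07e-32 and had adjusted p = 0.10 with an estimated correlation. Without C replicate 1 the calls of Fos, Fosb, Hspa1b and Arc stayed, and those of the other 17 genes ended, with adjusted p from 0.0522 for Tnnc2 to 0.170 for Pla2g4e. Without other libraries calls ended with adjusted p up to 0.265, for Nr4a1 without C replicate 3, and under other settings up to 0.490, for Pvalb with voom. In the immediate early list 5 of 25 genes rose and 0 fell (12 rose and 1 fell when adjusted over the list alone; camera, adjusted p = 1.77e-10; adjusted p = 0.47 with an estimated correlation).

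In 13 further lists that passed camera in DKO versus C at most 1 gene passed limma. Extracellular matrix, fibroblast, macrophage, mural cell, neuron and glia, angiogenic, ion channel, epicardium and neutrophil lists passed as higher, with camera adjusted p from 6.10e-08 to 0.0283. With an estimated correlation these 9 lists had adjusted p from 0.47 to 0.73. In DKO 3 the mean log2 value against C was negative for extracellular matrix (-0.12), fibroblast (-0.08), mural cell (-0.17), angiogenic (-0.16) and epicardium genes (-0.05), while DKO 1 and DKO 2 lay at 0.26 to 0.75 for these lists. Fatty acid oxidation (camera, adjusted p = 1.70e-13), oxidative phosphorylation (camera, adjusted p = 1.92e-14), cardiac stress (camera, adjusted p = 0.000174) and contractile genes (camera, adjusted p = 0.000259) were lower, and had adjusted p from 0.47 to 0.69 with an estimated correlation. Mean values of oxidative phosphorylation genes against C were -0.24 in DKO 1, -0.84 in DKO 2 and -0.09 in DKO 3, and those of contractile genes -0.30, -0.68 and 0.06. The contractile call ended without DKO replicate 2 (adjusted p = 0.110), the library that stood apart, and under quantile normalisation (adjusted p = 0.0921). The mural cell call ended without DKO replicate 1 (adjusted p = 0.103), and the neuron and glia call without C replicate 3 (adjusted p = 0.0522) or DKO replicate 1 (adjusted p = 0.123). The ion channel call ended without C replicate 1 (adjusted p = 0.104), DKO replicate 1 (0.151) or DKO replicate 3 (0.158), and with the length and GC trend removed (0.198). The angiogenic call ended without C replicate 2 (adjusted p = 0.15), DKO replicate 1 (0.104) or DKO replicate 2 (0.575). The epicardium call ended without C replicate 3 (adjusted p = 0.243), DKO replicate 1 (0.228) or DKO replicate 2 (0.101). The neutrophil call ended without C replicate 2 (adjusted p = 0.0795), C replicate 3 (0.0522), DKO replicate 2 (0.168) or DKO replicate 3 (0.0694). The remaining 15 lists did not pass, with camera adjusted p from 0.0683 to 0.99. The count of changed genes was 4 without C replicate 1, 12 without C replicate 3 and 90 without DKO replicate 3.

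In DKO against KO, 17 of 22 cardiac stress, 24 of 36 extracellular matrix and 19 of 44 hypoxia response genes were lower, and 10 of 42 oxidative phosphorylation genes were higher. These list calls had adjusted p = 0.11, adjusted p = 0.47, adjusted p = 0.0499 and adjusted p = 0.71 with an estimated correlation. Myh7 was 57.7 ± 20.9 in DKO against 1213 ± 8.99 in KO. It fell by 4.43 on the log2 scale (limma, adjusted p = 6.33e-06). Nppa fell by 2.85 on the log2 scale, from 2023 ± 565 to 289.3 ± 122.8 (limma, adjusted p = 0.000892). Tesc was 4.91-fold higher in DKO, at 360.9 ± 87.9 against 71.2 ± 6.59 (limma, adjusted p = 0.000197). Phkg1, a phosphorylase kinase subunit gene, was 3.98-fold higher, at 25.1 ± 2.65 against 5.77 ± 2.56 (limma, adjusted p = 0.000699). Casq1, encoding a calsequestrin, fell by 2.78, from 66.9 ± 17.9 to 9.21 ± 3.75 (limma, adjusted p = 0.000281).

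Of 22 cardiac stress genes 17 were lower in DKO than in KO and 0 higher (21 lower when adjusted over the list alone), with a median log2 fold change of -2.17. The list had camera adjusted p = 2.33e-19 and adjusted p = 0.11 with an estimated correlation. Of 36 extracellular matrix genes 24 were lower and 0 higher (30 lower when adjusted over the list alone; camera, adjusted p = 7.44e-18; adjusted p = 0.47 with an estimated correlation). Postn was at 28.5 ± 8.06 in DKO and Ltbp2 at 4.20 ± 1.19. In the hypoxia response list 19 of 44 genes were lower and 0 higher (21 lower and 1 higher when adjusted over the list alone), among them Loxl2 at 13.1 ± 1.43 and Slc16a3 at 3.17 ± 0.748 in DKO. The list had camera adjusted p = 1.33e-09 and adjusted p = 0.0499 with an estimated correlation. Of 28 proliferation genes 13 were lower and 1, Cenpf, higher (15 lower and 1 higher when adjusted over the list alone; camera, adjusted p = 1.78e-08; adjusted p = 0.0499 with an estimated correlation). Of 22 integrated stress response genes 5 were lower (6 when adjusted over the list alone), with Gdf15 at 16.7 ± 3.35 in KO and 1.55 ± 0.693 in DKO (camera, adjusted p = 0.0131; adjusted p = 0.47 with an estimated correlation). Of 26 glycolysis genes 6 were lower, Slc2a1 among them at 7.36 ± 1.02 in DKO, and 1, Pfkfb1, higher (the same numbers when adjusted over the list alone). That list had camera adjusted p = 0.0411 and adjusted p = 0.75 with an estimated correlation, and its call ended without DKO replicate 2 (adjusted p = 0.543) or KO replicate 3 (adjusted p = 0.201). The mean of the glycolysis list was -0.03, -0.41 and 0.08 in DKO 1 to 3, and 0.02 and 0.22 in KO 1 and KO 3. Hif1a was 26.9 ± 4.53 in DKO (limma, adjusted p = 0.00411 against KO; adjusted p = 0.0539 without KO replicate 1). Wt1 at 4.97 ± 1.44 (limma, adjusted p = 0.21) and Epas1 at 293.8 ± 47.5 (limma, adjusted p = 0.90) did not differ past the threshold.

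Higher in DKO than in KO were 10 of 42 oxidative phosphorylation genes, with 0 lower (18 when adjusted over the list alone; camera, adjusted p = 9.16e-07; adjusted p = 0.71 with an estimated correlation). The list's mean log2 value against C was -0.24 in DKO 1 and -0.09 in DKO 3, but in DKO 2, the library that stood apart, it was -0.84, at the level of KO 1 (-0.83) and KO 3 (-0.94). Of 13 mitochondrial transcripts 5 were higher and 0 lower (10 when adjusted over the list alone; camera, adjusted p = 1.98e-06; adjusted p = 0.58 with an estimated correlation). Of 31 fatty acid oxidation genes 6 were higher and 0 lower (8 higher and 1 lower when adjusted over the list alone; camera, adjusted p = 0.0283; adjusted p = 0.78 with an estimated correlation). The mean of the fatty acid oxidation list was -0.25 in DKO 1 and -0.22 in DKO 3, and in DKO 2 it was -0.91, below KO 1 (-0.85) and KO 3 (-0.62). Ucp3 was at 60.8 ± 11.1 in DKO against 18.3 ± 2.92 in KO. The fatty acid oxidation call ended under quantile normalisation (adjusted p = 0.235) and without DKO replicate 1 (0.193), DKO replicate 3 (0.324) or KO replicate 1 (0.223). Of 13 adipocyte genes 2 were higher (5 when adjusted over the list alone; camera, adjusted p = 0.00548; adjusted p = 0.47 with an estimated correlation; adjusted p = 0.0525 without KO replicate 1). Of 24 endothelium genes 2 were higher (also when adjusted over the list alone; camera, adjusted p = 0.0286; adjusted p = 0.78 with an estimated correlation). The endothelium call ended without DKO replicate 1 (adjusted p = 0.0850), DKO replicate 2 (0.414) or KO replicate 1 (0.0550). The mean of the endothelium list was 0.26 in DKO 1 and 0.56 in DKO 2, and in DKO 3 it was -0.31, below KO 1 and KO 3 (-0.18 in each). The remaining 19 lists did not pass, with camera adjusted p from 0.0934 to 0.99.

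In all, 1599 of 13544 genes changed between DKO and KO in limma, 823 higher and 776 lower in DKO, and 648 of them by at least 2-fold. Of the list calls 2, hypoxia response and proliferation, held with an estimated correlation. The count was 603 without KO replicate 1, 334 without KO replicate 3 and 730 when the C libraries were left out of the fit.

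Changes in KO and in DKO against C were also set side by side. Higher in both were 3 genes (Fos, Hspa1a and Hspa1b), where independent lists of these sizes share 0.690, and lower in both were 10, where independent lists share 0.771. The call of Fos in KO versus C ended without C replicate 1 (limma, adjusted p = 0.0799), C replicate 3 (0.129), KO replicate 1 (0.276) or KO replicate 3 (0.111). It also ended with a pseudocount of 5 (limma, adjusted p = 0.0772), quantile normalisation (0.0654), no trend (0.0592), a robust fit (0.0503), voom (0.0504) and DESeq2 (0.101). The overlap was 1 gene without C replicate 1, 7 without C replicate 3, 8 without DKO replicate 2 and 38 without DKO replicate 3. The 10 were Pdk4, Shld1 and the 8 skeletal muscle genes named above. Groups simulated without any change against the same 3 controls shared 0.02 higher and 0.05 lower genes on average over 100 draws. The covariance of the log2 fold changes was 0.0471 against 0.0213 in the simulation, a difference of 0.0258. Their correlation was 0.304 against 0.447 in the simulation, a difference of -0.143. The controls are too few to be divided, so part of the excess may come from the shared C libraries. Measured from KO instead, 571 genes were higher in KO than in both C and DKO and 549 were lower than in both, with the 2 KO libraries shared by both comparisons. Independent lists of these sizes share 53.5 and 57.7. Groups simulated without any change shared 0 and 0.03 such genes on average. Draws without change call few genes, so small overlaps in them were fixed in advance, here and against C.

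**Figure D3:**
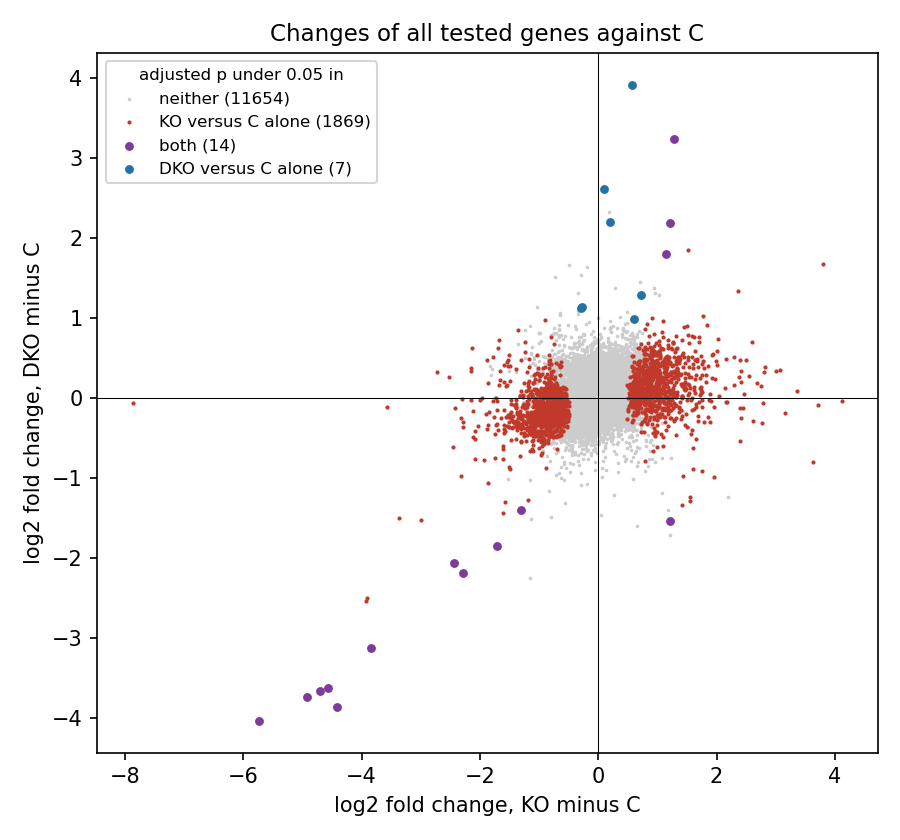
Log2 fold change of each of the 13544 tested genes in KO minus C (horizontal axis) and DKO minus C (vertical axis), with points coloured by the comparison in which the gene passed limma's adjusted p of 0.05. Most genes that passed spread along the horizontal axis, and the 10 genes lower in both comparisons lie at the lower left.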

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

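Mt2, which encodes a metallothionein, was the gene that passed limma's threshold in opposite directions against C in the KO and DKO libraries, and this difference between the groups drew attention to it. Its level was 33.7 ± 6.75 (SD, n = 3) in units of the deposited signal in C, 79.7 ± 22.3 (n = 2) in KO and 11.2 ± 3.45 (n = 3) in DKO, and no library of a group overlapped with those of another. The log2 difference was 1.21 for KO minus C (limma, adjusted p = 0.0122), -1.54 for DKO minus C (limma, adjusted p = 0.0258) and -2.75 for DKO minus KO. As the gene was picked because its calls against C went in opposite directions, the last value restates that choice and is no independent test. Over the 24 alternatives the DKO minus KO value ran from -3.36 to -2.39, with limma, edgeR or DESeq2 adjusted p from 4.13e-20 to 0.00513. The call in KO versus C ended without C replicate 1 (limma, adjusted p = 0.0523) or KO replicate 3 (limma, adjusted p = 0.156). The call in DKO versus C ended without C replicate 1 (limma, adjusted p = 0.0659), 2 (0.123) or 3 (0.155) or without DKO replicate 1 (0.0507). It also ended with no trend (limma, adjusted p = 0.0636) and, among alternatives chosen after seeing the data, with voom (0.0508) and the length and GC trend removed (0.0803). No explanation was tested for this gene.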

How the results depend on the processing

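Without mitochondrial transcripts, with voom, and with the length and GC trend removed are alternatives chosen after seeing the data. In KO versus C 1883 genes changed, and 3527 with library weights, 3606 with the 2 groups alone, 713 at a log2 fold change of at least 1, 696 at adjusted p 0.01, 2894 at adjusted p 0.10, and 449 to 2966 without a library. In DKO versus C 21 changed, and 13 with a pseudocount of 5, 7 at adjusted p 0.01, 34 at 0.10, 69 with DESeq2, 7 with voom and 4 to 90 without a library. In DKO versus KO 1599 changed, and 730 with the 2 groups alone, 648 at a log2 fold change of at least 1, 505 at adjusted p 0.01, 2578 at 0.10 and 334 to 1991 without a library. Where libraries were left out, fewer samples were fitted, and a lone KO library was assumed to vary like the other groups; otherwise the cause was not tested. The recovered reads gave 2045, 25 and 1692 genes with edgeR. No gene called in both the main and another setting turned direction. Median centring gave 43.3% of calls higher in KO versus C, against 49.6%.

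Gene lists numbered 14, 15 and 11 in the 3 comparisons, 0, 0 and 2 with an estimated correlation, 6, 1 and 5 with fry, and 14 to 16, 13 to 17 and 10 to 13 without a library. The contractile list in KO versus C turned direction under quantile normalisation (adjusted p = 0.0804). The overlap of KO versus C and DKO versus C was 13 genes in the same direction, 1 without C replicate 1, 7 without C replicate 3, 8 without DKO replicate 2 and 38 without DKO replicate 3. Vhl stayed within 0.05 to 0.20 in KO versus C, past the threshold in none of the 24 alternatives. Epas1, not past the threshold in any comparison, changed sign under quantile normalisation (0.11 in KO versus C, -0.12 in DKO versus KO). Without a library Epas1 ran from -0.202 to 0.0161 in DKO versus C and from -0.0654 to 0.185 in DKO versus KO. Of the values of called named genes under alternatives, 139 of 1960 in KO versus C (82 genes), 101 of 501 in DKO versus C (21 genes) and 126 of 1909 in DKO versus KO (80 genes) lost their call.

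The replicate number was not taken to pair the samples. C and DKO with the same number correlated at 0.19, -0.27 and 0.14, C and KO at 0.22 and 0.14, and DKO and KO at -0.01 and 0.10. Pairs with different numbers ran from -0.36 to 0.21. These values neither show nor exclude a pairing. With the replicate block 1794, 21 and 1269 genes, 14, 16 and 10 lists and an overlap of 15 genes were called, and Vhl was at 0.12. Sex as a covariate was not run, since the Y-linked genes were present at similar levels in all 8 libraries.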

Other observations

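The test for the share of cardiomyocytes was chosen after the result was seen, as were the ribosomal protein genes and the trend of length and GC content. Further gene groups that did not pass as lists in KO versus C held genes that changed. Among 32 ion channel and conduction genes 6 rose and 3 fell in KO (7 and 3 when adjusted over the list alone; camera, adjusted p = 0.13). Kcne1, a regulatory subunit gene of cardiac potassium channels, rose from 7.28 ± 3.03 (SD, n = 3) in units of the deposited signal in C to 40.6 ± 3.11 (n = 2) in KO and was 4.44 ± 0.176 (n = 3) in DKO. The potassium channel genes Kcnv2 (10.97 ± 2.06 in C, 1.94 ± 1.21 in KO) and Kcnj3 (28.2 ± 3.93 in C, 8.16 ± 1.88 in KO) fell. Of 18 circadian clock genes 3 rose and 1 fell (6 and 1 when adjusted over the list alone; camera, adjusted p = 0.11). Whether the time of collection differed between the groups was not tested. Arntl, which encodes the clock activator BMAL1, fell from 11.2 ± 2.73 to 3.56 ± 0.00641 and was 10.1 ± 0.867 in DKO, while Bhlhe41 rose from 10.5 ± 1.14 to 30.9 ± 2.17 and was 11.5 ± 2.08 in DKO.

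Of 10 neuron and glia genes 2 rose and 2 fell in KO (3 and 5 when adjusted over the list alone; camera, adjusted p = 0.54). Uchl1 rose from 9.42 ± 2.14 in C to 23.9 ± 1.85 in KO. Of 27 angiogenic signalling genes 5 rose and 0 fell (the same numbers when adjusted over the list alone; camera, adjusted p = 0.16), among them Esm1, a gene of endothelial tip cells, from 1.297 ± 0.616 to 7.67 ± 3.82. Of 22 integrated stress response genes 4 rose and 1 fell (6 and 1 when adjusted over the list alone; camera, adjusted p = 0.068), with the amino acid transporter gene Slc7a5 going from 3.18 ± 0.498 to 10.1 ± 0.687. Ndufa4l2, in the mural cell list and also in the hypoxia response list, rose from 22.3 ± 3.34 to 66.2 ± 6.51 and was 27.2 ± 5.69 in DKO. These genes passed the threshold in KO versus C under each alternative in which they were tested.

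The fall of oxidative phosphorylation genes in KO was weighed against 2 explanations. As transcripts of this list are short (median 1404 bases, 3380 over all tested genes), 10000 random lists matched on length and level were drawn: their median log2 fold change centred on -0.54 with a lower 2.5% limit of -0.71, and the list lay below it at -0.96. The list thus fell more than the matched lists, which could hold ribosomal protein genes that also fell and were drawn gene by gene. How much of the fall length bias accounts for can therefore not be told. With the trend of length and GC content removed, the list's median became -0.70, with 21 of 42 genes still lower past the threshold. For a lower share of cardiomyocytes as the whole cause, the contractile median was compared. It lay above that of oxidative phosphorylation by 0.59 (95% bootstrap interval 0.26 to 0.75 over genes, not over libraries). The 2 lists were not matched on transcript length, and lists matched to oxidative phosphorylation already centred on -0.54. The contractile list also holds Myh7, which rose, so this gap cannot decide the question. What stays open is a difference due to the group itself, as a hypothesis, length bias, and a lower share of cardiomyocytes as a part or the whole of the fall. Scaling stays open as well, as the list's median ran from -1.01 with median centring to -0.59 with quantile normalisation.

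Gm8730, a processed pseudogene on chromosome 8 (102864845 to 102865798, GRCm38) chosen after its values were seen, had 0 reads in both KO libraries, 237.3 ± 17.1 in C and 229.1 ± 40.5 in DKO, at least 4291-fold lower in KO than in C against 3 reads over the group. Its nearest annotated gene, Rplp0, shares 62.8% of its 31-base words and was 659.2 ± 39.2 in KO against 495.9 ± 36.7 in C (limma, adjusted p = 0.20, and 0.00667 to 0.50 over the 24 alternatives). Both KO libraries exceeded the highest C library, yet the smaller gain was 135.6. Reads moved to Rplp0 would need a gain of 237.3 if Rplp0 itself did not change. The 80 cytosolic ribosomal protein genes had a median log2 fold change of -0.75, so that baseline is uncertain. The summed signal of Gm8730 and Rplp0 was 685.4 to 772.8 in the C libraries, 686.9 in KO 1 and 631.5 in KO 3. A shift of reads to Rplp0 can neither be excluded nor shown, so the fold value of Gm8730 need not be a loss of expression. A stretch of another genetic background was looked for around Gm8730, the similar pseudogene Gm9625 (11.5 ± 2.97 in C, 0.0382 ± 0.0295 in KO) and Rad9b. Of 124 genes within 2 Mb, 8.87% changed in KO against 13.9% of other genes (one-sided Fisher exact test, p = 0.97). Such a stretch need not change the levels of its neighbours, so this test cannot exclude it. A sequence variant in the gene itself was not tested.

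Skeletal muscle genes (13 of the 15 in the list) were lower in KO and in DKO than in C, and skeletal muscle tissue in the C samples is a candidate source. If so, a second list of skeletal muscle genes should order the C libraries as the first list does (C 3, C 1, C 2), and 6 of its 8 tested genes did, where chance gives 1 in 6 (one-sided exact binomial test over genes, which are not independent, p = 0.000441). The most abundant genes of fast fibres that KO nearly lacked were Myh4 at 127.6, Atp2a1 at 81.3 and Tnnt3 at 73.4 in C 3. However, 4 of the 15 genes of the first list and 6 of the 8 of the second were at or above 1 in both KO libraries and so are expressed in this heart tissue, and 2 of the first are in another list. Mybpc2 and Casq1 of the first list were instead higher in KO 1 and KO 3 than in every C library. Mybpc2 was at 90.1 and 68.5 against 25.9 to 40.7, and Casq1 at 79.6 and 54.3 against 19.1 to 24.0. Muscle tissue in the C samples would not raise these genes in KO. A change of the skeletal muscle genes in heart muscle itself in both groups stays open.

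In DKO versus C the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real grouping gave 21 genes, and 1 of the splits, the real one, gave as many, with 0 as the highest of the other splits. It gave 15 gene lists, and 3 of the splits gave as many, with 18 as the highest of the others.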
